A study of Mus musculus with 6 samples.

How the data were processed

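Retinas of mice at postnatal day 17 were dissociated, enriched with CD31 or CD45 beads and profiled with Chromium 3' v3.1 chemistry on an Illumina HiSeq4000, per the labels. The 6 libraries cover 3 conditions (OIR with control IgG, OIR with antibodies against ROBO1 and ROBO2, and room air) and 2 enrichments, with 1 library per group. Antibodies were given at 10 mg/kg on days 12, 14 and 16, and the target was 10000 cells per library, per the labels. The deposited values are raw UMI counts per gene and barcode for 32285 genes, as whole numbers with no cell filter applied. The header of each matrix names Cell Ranger 7.1.0, while the submitters' processing notes name Cell Ranger 2.1.1, Seurat 4 and build mm10. Whether intron reads were counted, and whether the CD31 and CD45 libraries of a condition came from the same retinas, is not given in the sources used here. The kinase inhibitor that the treatment protocol also describes was not used here. Gene positions were taken from the GENCODE M21 annotation of GRCm38, and 38 symbols shared by several identifiers were kept apart by identifier.

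Cells were called per library as barcodes with at least 10% of the 99th percentile of UMIs among the 10000 largest barcodes, with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. The UMI threshold came to 8682 (IgG, CD31), 4063 (IgG, CD45), 5724 (room air, CD31), 2626 (room air, CD45), 5055 (anti-ROBO, CD31) and 4364 (anti-ROBO, CD45). Of 10881 barcodes over the threshold 10377 passed the filters, and Scrublet called 51 of them (0.491%) doublets, between 0.0654% and 1.29% per library; how many it missed was not tested. The 10326 remaining cells had median totals of 20963, 14781.5, 15181.5, 9803, 10878.5 and 15098 UMIs in the same order of libraries. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave the clusters. Each cluster was named by the highest mean score among marker lists of 23 cell classes, with at least 3 markers detected and a mean score of at least 1, and left unnamed where more markers of another class than of its own were among its 10 leading genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used, with random seed 1.

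UMIs were summed over the cells of a class in a library and expressed as counts per 1000000 (CPM) with exact Poisson 95% intervals. Ratios carry the exact conditional interval of 2 Poisson counts, and against a count of 0 a floor of 3 counts was used. Where 0 was counted, the level or share that 3 counts would give is stated as allowed. It lies below the upper end of the 95% interval. A class was compared where both libraries held at least 100 of its cells. Log2 values are log2((CPM + 10) / (CPM + 10)), and a list's value is the median over members with at least 20 UMIs in both libraries together, with its interval from 1000 Poisson redraws. The lists covered tip cell, arterial, venous, barrier, vesicle transport, VEGF with SLIT and ROBO, Notch, TGF-beta and BMP, basement membrane, leukocyte adhesion, cell cycle, hypoxia, glycolysis, interferon, MHC class II and dissociation response for endothelial cells. Those for microglia added homeostatic and activated microglia, inflammatory, myeloid angiogenic, lipid handling, PI3K pathway, and complement and phagocytosis. Some lists share members, so their medians are not independent. Slc2a1, Ldha, Pgk1, Aldoa, Eno1 and Tpi1 are in both the hypoxia and glycolysis lists. Apoe, Lpl, Fabp5 and Lgals3 are in both the lipid-handling and activation lists. No statistical test between conditions, p-value or standard error is given, since with 1 library per group cells are not replicates of a condition. In counts simulated with known folds in 11064 genes at the depth of the endothelial comparison of IgG with room air, folds of 1.5, 2 and 4 came back with medians of 1.495, 1.99 and 3.97. There, 95.3% of unaltered genes had an interval that covered their true value. A list raised 2-fold came back with a median of 1.74, since the pseudocount shrinks ratios. The simulated counts were drawn as Poisson, as the intervals assume, so this coverage was built in. It does not cover UMIs spread unevenly between cells, for which these intervals can be too narrow.

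The marker and gene lists, the comparisons, the rule for named genes and most of the alternative settings were fixed before the data were examined; the conditions for naming a cluster by its markers were not. The rule took genes with at least 100 UMIs in both libraries together. In the higher library their CPM had to be at least 2 times that of the free-RNA profile. Where both libraries of the other enrichment held at least 100 cells of the class, the direction there had to be the same. The rule left out mitochondrial, ribosomal, haemoglobin, crystallin and unnamed genes and markers of another class. Of genes on the sex chromosomes it left out Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty. It named the 10 furthest genes each way (3 each way in other classes), the ROBO and SLIT genes, and up to 4 members of each list. Fcrls, Pmel, Arg1 and the other genes given as leading a cluster or a sub-cluster were named after their values were seen. The planned free-RNA profile, barcodes of 10 to 100 UMIs, turned out to hold swapped reads: 27.9 to 56.3% of these barcodes were called cells of another library, against 0.403 to 1.82% of barcodes of 100 to 300 UMIs, so the latter were added as an alternative. The free-RNA level of a gene in a class is its CPM in a profile times the share of free RNA estimated from photoreceptor genes, and the larger of the levels from both profiles is given unless both are. With IgG, in room air and with anti-ROBO the planned profile gave shares of 1.76, 3.16 and 3.95% in endothelial cells and 5.98, 8.31 and 9.02% in microglia. The profile of 100 to 300 UMIs gave 1.003, 1.41 and 2.08%, and 2.68, 3.095 and 3.49%. No direction is given for ROBO and SLIT genes under 2 times the larger level in both libraries compared, a separation made after 21 of 114 alternatives over 10 such gene comparisons had turned sign.

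Dividing cells were counted after each cell had been thinned to 1000 UMIs, as cells with UMIs of at least 2 of 13 core cell-cycle genes, and shares carry exact Clopper-Pearson 95% intervals. Intervals over redrawn cells come from 1000 draws of the cells of both libraries. Sub-clusters of endothelial cells and leukocytes were made from 1000 variable genes without the genes of the naming lists, with 20 components. Their resolution of 0.4 was picked after 0.4 and 0.8 had both been seen. A sub-cluster's name needed a list member among its 10 leading genes, a condition added after macrophages with Lyve1 and Mrc1 had been named by interferon genes (12.3% of leukocytes with IgG, 11.4% in room air, 13.03% with anti-ROBO). The same condition left unnamed a group of endothelial cells with Adgrg6 and Il1r1 (4.21, 3.01 and 10.4%) that had been named venous. Alternatives covered scaling, weight of cells, pseudocount, list minimum, free RNA, cell filters, doublets, clustering resolution, thinning depth and the other enrichment. Leaving out clusters (of endothelial cells and Müller glia), adding unnamed ones, other depth minimums, depth minimums without the Arg1 cluster's cells, a stricter doublet limit and the smaller CD45 libraries, with and without a sub-cluster, were chosen after seeing the data.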

Results

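Single-cell RNA sequencing libraries were made from retinas of mice at postnatal day 17. In oxygen-induced retinopathy (OIR), a model of ischaemic eye disease, pups breathe 75% oxygen from day 7 to day 12 and return to room air, after which new vessels grow out of place. The labels set 3 conditions side by side: OIR with control IgG, OIR with antibodies that block ROBO1 and ROBO2, and room air without treatment. ROBO1 and ROBO2 are receptors for the secreted SLIT guidance proteins. Each condition was split by magnetic beads into a CD31 library, enriched for endothelial cells, and a CD45 library, enriched for immune cells, with 1 library per group and 8 retinas behind each group. The libraries held 93092011 (IgG, CD31), 66832522 (IgG, CD45), 70896862 (room air, CD31), 48771571 (room air, CD45), 66010897 (anti-ROBO, CD31) and 75145029 (anti-ROBO, CD45) UMIs, that is, tagged molecules. With 1 library per group no spread between animals could be measured, so no statistical test between conditions was made. Each interval given is a 95% interval for counting error, except some in the closer look that are over redrawn cells. None covers the spread between animals.

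The bead fractions were enriched but not pure. After filtering, 10326 cells remained, and the CD31 libraries held 428 (IgG), 531 (room air) and 498 (anti-ROBO) endothelial cells among 1529, 1838 and 1448 cells. The CD45 libraries held 408, 337 and 471 microglia, the resident macrophages of the retina, among 1660, 1793 and 2058 cells. Müller glia, rods, cones and bipolar cells made up much of the remainder. Depth differed between the groups, with a median of 44690 UMIs per endothelial cell with IgG, 24735 in room air and 10046 with anti-ROBO, and the lowest UMI total called a cell was 8682, 5724 and 5055 in those libraries. Most room-air endothelial cells, 336 of 531, lay in a cluster led by Cxcl12 and Slco1c1 that held 16 of the IgG and 35 of the anti-ROBO cells. A cluster led by Apln and Esm1 held 133 IgG, 6 room-air and 57 anti-ROBO endothelial cells. A cluster led by Adgrg6 and Il1r1 and another led by Pmel and Myh11 took 79.4% and 100% of their cells from the anti-ROBO CD31 library, with 104 and 62 of its 498 endothelial cells.

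The first question was where the blocked receptors are expressed. Robo1 (ENSMUSG00000022883; GRCm38 chromosome 16, 72308306 to 73046095, plus strand, protein coding) stood at 60.7 CPM (57.7 to 63.8) in endothelial cells of the IgG CD31 library. Its level was 18.4 CPM (16.3 to 20.6) in room air and 37.3 CPM (34.1 to 40.8) with anti-ROBO, and the level that free RNA in the droplets would give, the larger of 2 estimates, was 1.23, 3.30 and 5.01 CPM. The smaller CD45 libraries gave 68.0, 17.9 and 30.9 CPM for Robo1 in 58, 57 and 81 endothelial cells. Robo4, the endothelial member of the family (chromosome 9, 37401897 to 37415115), stood at 158, 171 and 149 CPM in the CD31 libraries. Robo2 (chromosome 16, 73891839 to 74411825, minus strand) reached 3.08 (2.44 to 3.84), 1.41 (0.895 to 2.12) and 8.26 CPM (6.76 to 9.99) in endothelial cells of the CD31 libraries. Free RNA would give 2.45, 5.53 and 7.75 CPM by the planned profile and 3.303, 3.38 and 10.7 CPM by the profile of barcodes of 100 to 300 UMIs, so Robo2 was not detectable above free RNA there. In the 58 endothelial cells of the IgG CD45 library it stood at 11.96 CPM (8.46 to 16.4), against 2.90 CPM. Slit2, a ROBO ligand, stood at 11.0, 10.2 and 12.4 CPM in the CD31 libraries, against 5.48, 10.3 and 13.2 CPM by the planned and 8.91, 10.8 and 16.7 CPM by the other profile, and so lay under 2 times the larger free-RNA level in each library. Slit1 had 3, 0 and 2 UMIs and Slit3 had 38, 66 and 10 UMIs in endothelial cells.

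In microglia both blocked receptors stayed at or below the free-RNA level. Robo1 stood at 3.51 (IgG), 2.48 (room air) and 3.21 CPM (anti-ROBO) against free-RNA levels of 5.55, 7.82 and 8.05 CPM. Robo2 stood at 5.63, 4.51 and 5.16 CPM against 9.65, 9.07 and 15.3 CPM. Slit2 stood at 14.2, 10.4 and 10.0 CPM against 21.8, 14.8 and 22.8 CPM. Robo4 had 0 UMIs in all 3 CD45 libraries, which allows up to 0.319, 0.676 and 0.292 CPM. Neurons and glia carried more: over the 6 libraries Robo1 stood between 670 and 1581 CPM in amacrine cells, and Robo2 between 730 and 981 CPM in bipolar cells. Slit2 stood between 1190 and 2669 CPM in bipolar cells. In Müller glia Robo2 stood between 257 and 421 CPM, against free-RNA levels of 73.8 to 262 CPM.

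**Figure D1:**
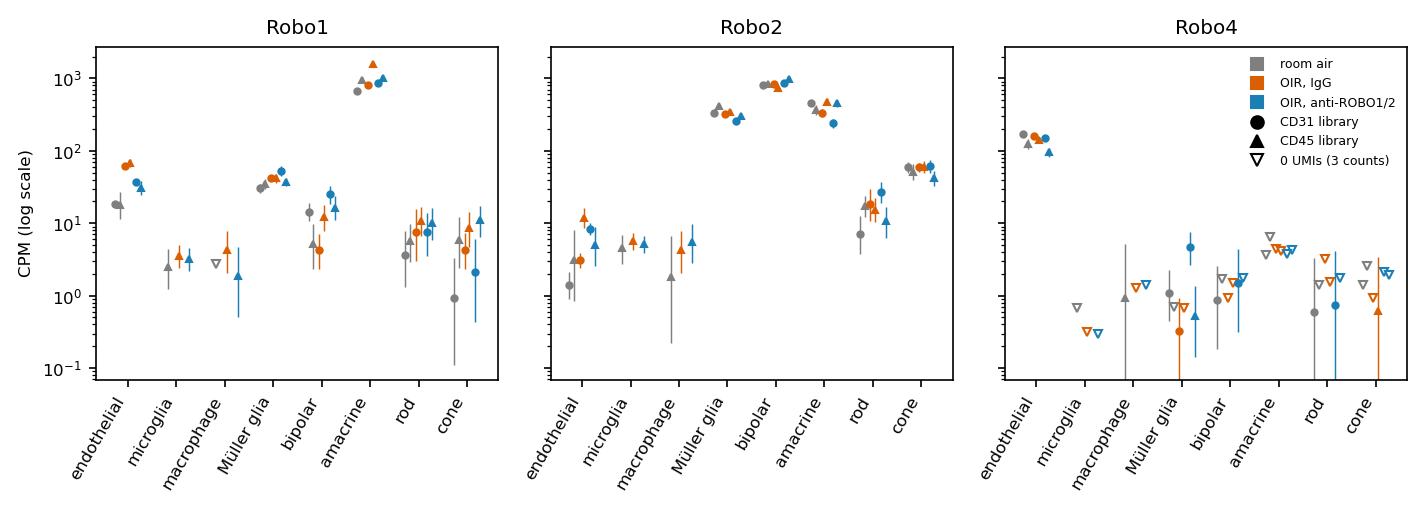
Levels of Robo1, Robo2 and Robo4 (CPM, log axis) by cell class in the CD31 (circles) and CD45 libraries (triangles), with 95% counting intervals as lines and open triangles for the level that 3 counts would give where there were 0 UMIs. Robo1 in endothelial cells of the CD31 libraries lies at 60.7 (IgG), 18.4 (room air) and 37.3 CPM (anti-ROBO).

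The second question was how endothelial cells differ between OIR with IgG and room air. Genes of cell division and of the endothelial tip cell, the migrating cell at the front of a sprout, were higher in the IgG library. Apln, the ligand of the apelin receptor and a tip-cell marker (chromosome X, 48025146 to 48034853), stood at 621 against 74.1 CPM, a ratio of 8.38 (7.91 to 8.90). Esm1, another tip-cell marker (chromosome 13, 113209659 to 113218098), stood at 201 against 25.8 CPM, a ratio of 7.80 (7.06 to 8.63). Top2a, a topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189), stood at 100.1 against 0.430 CPM, and Mki67, the Ki-67 antigen, at 66.9 against 0.860 CPM. Cxcl12, a chemokine (chromosome 6, 117168535 to 117181367), was lower with IgG, at 143 against 1619 CPM, a ratio of 0.0885 (0.0855 to 0.0916).

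By gene list, the median log2 ratio of IgG to room air in endothelial cells was 1.79 (1.74 to 1.86) for the cell cycle, with 25 of 25 measured members at least 1.5-fold higher. Its members Pclaf, Birc5 and Ube2c had ratios of 145 (73.5 to 337), 123 (64.6 to 269) and 85.3 (51.6 to 153). Outside the list, the linker-histone gene Hist1h1b had a ratio of 312 (143 to 851) and Cks2, a partner of cyclin-dependent kinases, 14.8 (12.02 to 18.4). In the 58 and 57 endothelial cells of the CD45 libraries the cell-cycle median was 0.70, and with a pseudocount of 1 it was 4.16. The tip-cell median was 1.55 (1.497 to 1.59), with 16 of 20 members at least 1.5-fold higher and 0 of 20 lower; Pgf, a VEGF-family growth factor, had a ratio of 81.0 (43.9 to 169) and Cxcr4 6.91 (6.02 to 7.95). Basement-membrane genes had a median of 0.83 (0.80 to 0.86) with 10 of 12 higher, among them Col18a1 (3.56, 3.34 to 3.79) and Loxl2 (4.19, 3.58 to 4.94). Glycolysis had a median of 0.79 (0.74 to 0.81), with 8 of 12 higher, among them the lactate exporter Slc16a3 (8.29, 5.78 to 12.3). The hypoxia list was mixed, with a median of 0.35 (0.28 to 0.43), 7 of 16 higher and 3 of 16 lower: Egln3 had a ratio of 10.1 (7.75 to 13.5) and Ndrg1 of 0.182 (0.161 to 0.205).

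Genes of the blood-retina barrier were lower with IgG than in room air, with a median of -1.03 (-1.07 to -0.95) and 13 of 17 members at least 1.5-fold lower. Slco1c1, a thyroid-hormone carrier, had a ratio of 0.193 (0.186 to 0.201), Slco1a4 0.214 (0.209 to 0.218), Slc16a1 0.265 (0.259 to 0.272), the efflux pump Abcb1a 0.337 (0.328 to 0.346) and the glucose carrier Slc2a1 0.477 (0.470 to 0.484). In the vesicle-transport list, with a median of 0.33 (0.29 to 0.37), Plvap, a protein of fenestrated and leaky vessels, had a ratio of 6.49 (5.64 to 7.52). Other lower genes were Sema3c (0.103, 0.0946 to 0.111), Sgpp2 (0.0902, 0.0761 to 0.106), Clic5 (0.105, 0.0920 to 0.119), Nebl (0.164, 0.156 to 0.173), Atp10a (0.167, 0.156 to 0.178), Ly6c1 (0.178, 0.175 to 0.182), Ccdc141 (0.182, 0.176 to 0.188) and Spock2 (0.198, 0.194 to 0.202). Interferon genes were lower, with a median of -1.16 (-1.23 to -1.09) and 11 of 15 lower, among them Rsad2 (0.0947, 0.0756 to 0.117) and Ifit3 (0.0988, 0.0807 to 0.120). The TGF-beta and BMP list had a median of -0.64 (-0.67 to -0.60), with Id1 at a ratio of 0.378 (0.368 to 0.388) and Bmp6 at 4.82 (4.12 to 5.68).

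Medians of the remaining lists between IgG and room air were 0.36 (0.28 to 0.44) for venous, -0.26 (-0.33 to -0.16) for arterial, -0.31 (-0.39 to -0.25) for Notch, 0.13 (0.05 to 0.16) for leukocyte adhesion, -0.04 (-0.09 to 0.02) for VEGF, SLIT and ROBO and -0.04 (-0.11 to 0.03) for MHC class II genes. Within them members went both ways: Gja4 had a ratio of 3.07 (2.73 to 3.46) and Sox17 of 0.456 (0.437 to 0.475), both arterial, Hey1 0.360 (0.328 to 0.394) and Nrarp 2.24 (2.09 to 2.41), both of the Notch pathway, and Flt1, a VEGF receptor, 0.435 (0.429 to 0.440). The adhesion molecules Sele and Icam1 had ratios of 9.19 (5.62 to 16.03) and 2.19 (2.04 to 2.35). Immediate-early genes that dissociation is known to induce were also lower with IgG, with a median of -1.10 (-1.20 to -1.04), Jun at 0.310 (0.301 to 0.319) and Fosb at 0.292 (0.272 to 0.314).

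The third question was how endothelial cells differ between anti-ROBO and IgG after OIR. This comparison shares its IgG library with that of IgG and room air. A peculiarity of that library would move values in opposite directions in both comparisons, and this was not tested. Cell-cycle genes and part of the tip-cell genes were lower in the anti-ROBO library. Esm1 stood at 65.2 against 201 CPM, a ratio of 0.324 (0.301 to 0.349), and Angpt2, a vessel-destabilising ligand of TIE2 (chromosome 8, 18690263 to 18741562), at 111 against 257 CPM, a ratio of 0.434 (0.409 to 0.459). Top2a stood at 34.5 against 100.1 CPM, a ratio of 0.345 (0.311 to 0.382), and Mki67 at 23.1 against 66.9 CPM. Several barrier carriers were higher, among them Slc16a1 (2.70, 2.62 to 2.77), Slco1a4 (2.26, 2.20 to 2.32) and Slc2a1 (1.80, 1.77 to 1.83). Without both clusters taken mostly from the anti-ROBO CD31 library, which hold 166 of its 498 endothelial cells, the log2 values of Slc16a1 and Slc2a1 were 1.25 and 0.79 in place of 1.404 and 0.84.

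The median log2 ratio of anti-ROBO to IgG for the cell cycle in endothelial cells was -0.87 (-0.94 to -0.82), with 21 of 25 members at least 1.5-fold lower. Its members Pclaf, Ube2c, Birc5 and Cdk1 had ratios of 0.331 (0.292 to 0.374), 0.361 (0.322 to 0.404), 0.388 (0.344 to 0.436) and 0.398 (0.357 to 0.442). Outside the list, Hist1h1b had a ratio of 0.279 (0.251 to 0.310) and Odc1, of polyamine synthesis, 0.412 (0.391 to 0.434). In the CD45 libraries, with 81 and 58 endothelial cells, the cell-cycle median was -0.29. The tip-cell median was -0.28 (-0.34 to -0.22), with 5 of 20 lower and 1 of 20 higher; Pgf had a ratio of 0.396 (0.345 to 0.454) and Apln of 0.483 (0.466 to 0.500). That tip-cell median was -0.18 without both clusters taken mostly from the anti-ROBO CD31 library, and -0.60 where each cell had equal weight. Glycolysis, hypoxia and basement membrane had medians of -0.35 (-0.37 to -0.32), -0.21 (-0.26 to -0.17) and -0.16 (-0.19 to -0.14), but few members differed 1.5-fold: 0 of 12, 2 of 16 and 0 of 12 were lower, and 1 of 12, 2 of 16 and 0 of 12 higher.

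On the higher side, the barrier list had a median of 0.55 (0.53 to 0.63), with 8 of 17 members at least 1.5-fold higher and 0 of 17 lower, the arterial list 0.37 (0.28 to 0.45) with 4 of 13 higher, and the interferon list 0.35 (0.28 to 0.44) with 4 of 15 higher. Mgp and Bmx, both arterial, had ratios of 3.75 (3.58 to 3.94) and 2.31 (2.08 to 2.56), and Ifit3 5.26 (4.24 to 6.55). Among the genes furthest to the higher side by the fixed rule were Paqr5 (4.55, 4.20 to 4.94), Zbtb16 (4.92, 4.33 to 5.604), Sult1a1 (5.29, 4.59 to 6.103), the interleukin-1 receptor Il1r1 (3.32, 3.02 to 3.64), Tsc22d3 (2.71, 2.59 to 2.85), Pik3ip1 (3.09, 2.75 to 3.48), Lamc3 (8.37, 6.27 to 11.4) and Ccdc141 (2.40, 2.30 to 2.501). Without both clusters taken mostly from the anti-ROBO library, the barrier, arterial and interferon medians were 0.53, 0.47 and 0.34, but the venous median was 0.07 in place of 0.34, that of leukocyte adhesion -0.0057 in place of 0.18 and that of basement membrane -0.05 in place of -0.16. The log2 value of Il1r1 was then 0.65 in place of 1.44 and that of the venous gene Ackr1 was 0.25 in place of 0.68. Medians for the remaining lists were 0.34 (0.29 to 0.39) for venous, 0.23 (0.19 to 0.34) for Notch, 0.22 (0.15 to 0.26) for TGF-beta and BMP, 0.18 (0.11 to 0.23) for leukocyte adhesion, 0.05 (0.00 to 0.10) for vesicle transport, -0.09 (-0.13 to -0.04) for VEGF, SLIT and ROBO, -0.10 (-0.15 to -0.04) for MHC class II and 0.36 (0.28 to 0.48) for the dissociation response. Pmel, a pigment-cell gene, stood at 67.6 CPM in anti-ROBO endothelial cells and 0.663 CPM in IgG cells.

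Dividing endothelial cells were counted after every cell had been thinned to 1000 UMIs, by at least 2 of a set of core cell-cycle genes. They made up 10.3% (44 of 428 cells, 7.57 to 13.6%) with IgG and 2.81% (14 of 498, 1.55 to 4.67%) with anti-ROBO. In room air 0 of 531 were counted, which allows up to 0.565%. The difference between IgG and room air was 10.3 points (7.65 to 13.5), and that between anti-ROBO and IgG -7.47 points (-10.9 to -4.33). The last difference was -3.75 points where every library used the same minimum of 1000 UMIs and 500 genes per cell. That minimum gave 2549 anti-ROBO and 708 IgG endothelial cells, in place of 498 and 428. The main anti-ROBO values thus rest on a small part of the barcodes that clustered as endothelial there. In the CD45 libraries 4 of 58 (IgG), 1 of 57 (room air) and 1 of 81 (anti-ROBO) endothelial cells were counted, differences of 5.14 points (-3.48 to 14.8) between IgG and room air and -5.66 points (-15.3 to 1.19) between anti-ROBO and IgG, neither detectable at this number of cells. Rods, which do not divide, gave 0 of 68, 0 of 190 and 0 of 168 in the CD31 libraries at median depths of 11227, 7549.5 and 7216.5 UMIs, which allows up to 4.41, 1.58 and 1.79%. Müller glia gave 0 in the other 5 libraries but 6 of 150 (4%, 1.48 to 8.50%) in the anti-ROBO CD31 library, where all 6 also carried UMIs of the endothelial gene Pecam1. All 6 lay among the 40 cells of 1 Müller cluster, led by Optc. In it endothelial markers stood at 2452 CPM in that library, against 224 in the IgG (11 cells) and 1668 CPM in the room-air CD31 library (10 cells). The Müller clusters led by Gm11906 and by Prss56 had 1838 and 1666 CPM in the anti-ROBO and 1655 and 1551 CPM in the IgG CD31 library. In the CD45 libraries the Optc cluster had 271 (IgG), 386 (room air) and 524 CPM (anti-ROBO). High levels of these markers were thus not particular to the Optc cluster. Within it they were high in the anti-ROBO and room-air CD31 libraries only, and 2452 CPM was the highest value in any of these clusters.

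Sub-clusters made without the genes of the fixed lists gave the same order for tip cells and dividing cells. The tip-cell sub-cluster held 31.8% of endothelial cells with IgG, 1.32% in room air and 11.2% with anti-ROBO. The cell-cycle sub-cluster held 19.2%, 0% (which allows 0.565%) and 4.82%. A sub-cluster with photoreceptor and myeloid transcripts, Lyz2 and C1qb among them, held 1.87%, 0.377% and 16.5%. Bead enrichment, the lowest UMI total and depth differ between these libraries and bear on each share.

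**Figure D2:**
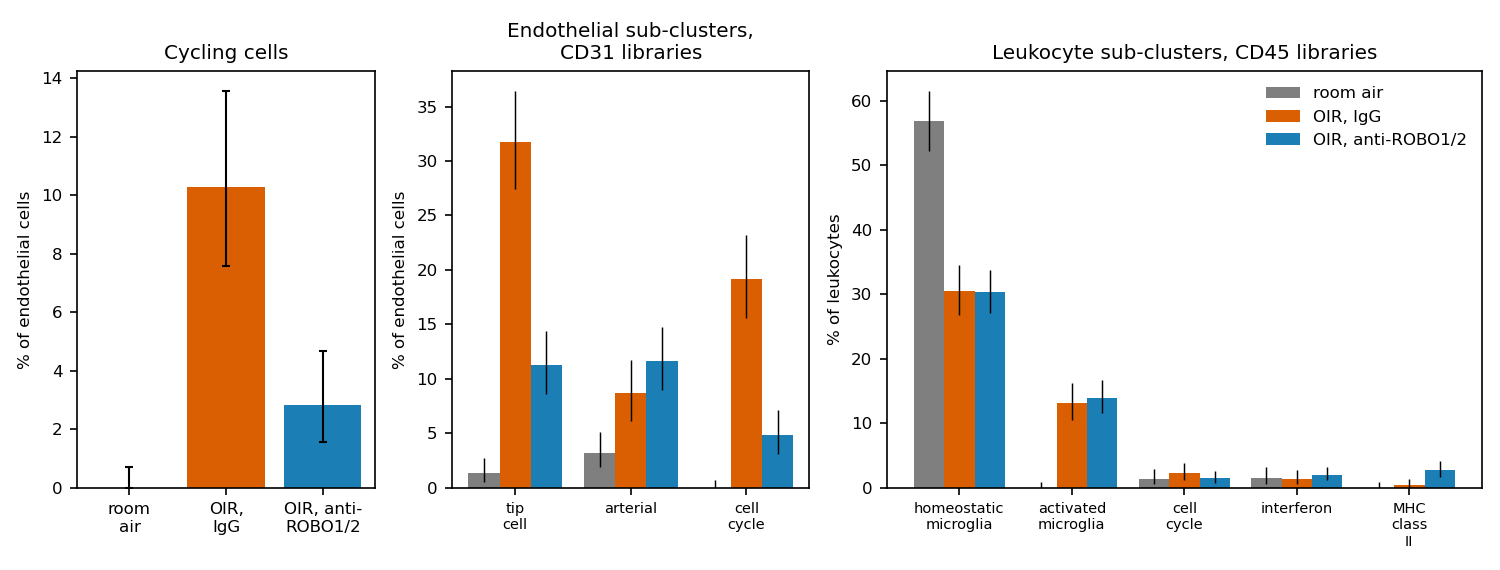
Share of dividing endothelial cells, and of cells in the named endothelial and leukocyte sub-clusters (percent of cells of 1 library, bars; 95% Clopper-Pearson intervals for counting error, lines). Dividing endothelial cells make up 10.3% with IgG, 2.81% with anti-ROBO and 0 of 531 in room air.

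The fourth question was how microglia differ between OIR with IgG and room air. Genes of lipid handling, glycolysis, hypoxia and microglial activation were higher with IgG, and 7 of 18 genes of resting microglia were at least 1.5-fold lower. The hypoxia and glycolysis lists share members, as do those of lipid handling and activation, so these are not separate results. Lgals3, which encodes galectin-3 (chromosome 14, 47367751 to 47386160), stood at 684 against 15.3 CPM, a ratio of 44.6 (35.2 to 57.6). Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), stood at 751 against 30.9 CPM, a ratio of 24.3 (20.5 to 29.02). Mmp12, a macrophage elastase (chromosome 9, 7344381 to 7369499), had 1868 UMIs with IgG and 0 in room air, at least 293-fold higher. Cx3cr1, the fractalkine receptor of resting microglia (chromosome 9, 119901616 to 120069879), stood at 723 against 2016 CPM, a ratio of 0.358 (0.347 to 0.370). Of the 408 IgG microglia 182 lay in a cluster led by Mmp12 and Hmox1 that held 13 of the 337 room-air cells; 212 and 279 lay in a cluster led by P2ry12.

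The lipid-handling list had a median log2 ratio of IgG to room air in microglia of 1.80 (1.69 to 1.86), with 7 of 8 measured members at least 1.5-fold higher, among them Lpl (4.38, 3.91 to 4.91) and Abca1 (3.75, 3.43 to 4.10). Glycolysis had a median of 1.46 (1.41 to 1.58) with 11 of 12 higher, led by Pgk1 (7.79, 6.93 to 8.79), and hypoxia 1.45 (1.39 to 1.54) with 13 of 16 higher, among them Egln3 (19.1, 13.2 to 28.6) and Bnip3 (10.1, 8.56 to 11.98). The activation list had a median of 1.00 (0.93 to 1.14) with 15 of 20 higher, among them Igf1 (7.13, 6.02 to 8.501) and Cst7 (7.73, 6.03 to 10.1). The myeloid angiogenic list had a median of 0.67 (0.59 to 0.77) with 7 of 14 higher, inflammatory genes 0.43 (0.35 to 0.46) with 5 of 14 higher, Il1b at 11.1 (8.06 to 15.9) among them, and interferon genes 0.38 (0.28 to 0.48) with 4 of 15 higher. Outside the lists, the apolipoprotein gene Apoc1 had a ratio of 37.1 (28.4 to 49.3), the lipid receptor Olr1 37.6 (17.2 to 103) and Ccl5 of 30.6 (23.2 to 41.4), with most of the room-air Ccl5 UMIs in 1 cell. Cartpt and Nefh, both neuronal genes, also met the fixed rule, but 98.9% and 89.5% of their UMIs in the higher library came from 1 cell each.

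The homeostatic list of resting microglia had a median of -0.44 (-0.46 to -0.41), with 7 of 18 members at least 1.5-fold lower with IgG, Tmem119 at 0.482 (0.454 to 0.512) among them, and 1 of 18 higher, Fcrls. Among other lower genes were Sncaip (0.294, 0.244 to 0.352), the prostaglandin-degrading enzyme Hpgd (0.393, 0.368 to 0.418), Numb (0.394, 0.369 to 0.421), Col27a1 (0.424, 0.376 to 0.479), Dnajb9 (0.442, 0.405 to 0.482), Cst3 (0.451, 0.448 to 0.454) and Jun (0.462, 0.452 to 0.472). The dissociation list had a median of -0.52 (-0.55 to -0.49). Medians nearer to 0 were 0.22 (0.15 to 0.30) for the cell cycle, 0.21 (0.19 to 0.23) for complement and phagocytosis, -0.16 (-0.26 to -0.09) for the PI3K pathway and -0.10 (-0.20 to -0.00) for MHC class II. Cd74, of the MHC class II list, had a log2 value of 1.37 that was -0.053 with at most 10% mitochondrial UMIs and -0.062 with called doublets kept. These settings also changed which cells were classed as microglia. They gave 416 and 429 IgG cells in place of 408, and 347 and 349 room-air cells in place of 337.

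The fifth question was how microglia differ between anti-ROBO and IgG after OIR. This comparison also shares its IgG library with that of IgG and room air. List medians lay between -0.24 and 0.29, and single genes differed more. Mmp12 stood at 487 against 198 CPM, a ratio of 2.45 (2.33 to 2.59), where 1 cell held 18.96% of the anti-ROBO and 15.7% of the IgG UMIs. Spp1 stood at 1205 against 751 CPM and Cx3cr1 at 1355 against 723 CPM, a ratio of 1.87 (1.82 to 1.93). Hmox1, the haem-degrading oxygenase (chromosome 8, 75093621 to 75100589), stood at 407 against 881 CPM, a ratio of 0.462 (0.445 to 0.480). Csf1, a growth factor of macrophages (chromosome 3, 107741048 to 107760469), stood at 42.1 against 96.9 CPM, a ratio of 0.435 (0.387 to 0.488). The Mmp12 cluster held 179 and the P2ry12 cluster 277 of the 471 anti-ROBO microglia.

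The largest list medians in this comparison of microglia were 0.29 (0.23 to 0.36) for interferon, with 1 of 15 measured members at least 1.5-fold higher, and -0.24 (-0.28 to -0.19) for inflammatory genes, with 3 of 14 lower. The inflammatory genes Cxcl2, Ccl4 and Tnf had ratios of 0.526 (0.486 to 0.569), 0.571 (0.554 to 0.589) and 0.652 (0.624 to 0.681). Activation had a median of -0.18 (-0.21 to -0.12), with 2 of 20 members at least 1.5-fold lower and 1 of 20 higher. The homeostatic list had one of -0.14 (-0.16 to -0.10), although 0 of 18 members were at least 1.5-fold lower and 2 of 18 higher, Cx3cr1 and Crybb1. This median was -0.33 with at most 10% mitochondrial UMIs and -0.34 with called doublets kept. In these settings 600 and 607 anti-ROBO cells were classed as microglia in place of 471, and 416 and 429 IgG cells in place of 408. The class thus took in cells of other clusters there, and which cells these were was not examined. Other medians were 0.13 (0.08 to 0.18) for lipid handling, 0.09 (0.04 to 0.13) for hypoxia, 0.07 (0.04 to 0.12) for glycolysis, -0.01 (-0.10 to 0.04) for angiogenic genes, -0.02 (-0.04 to 0.02) for complement and phagocytosis, 0.01 (-0.05 to 0.07) for the PI3K pathway, -0.08 (-0.17 to 0.01) for MHC class II, -0.08 (-0.14 to -0.03) for the cell cycle and 0.05 (-0.09 to 0.09) for the dissociation response. Higher genes by the fixed rule were AA467197 (3.31, 2.45 to 4.55), Apoc4 (2.57, 1.97 to 3.404), Peg10 (2.23, 1.68 to 2.996), Fkbp5 (1.94, 1.78 to 2.13), Rtp4 (1.85, 1.62 to 2.12), Hgsnat (1.73, 1.49 to 2.02) and Zfas1 (1.57, 1.44 to 1.70). Lower genes were the oxidative-stress genes Osgin1 (0.275, 0.215 to 0.349) and Srxn1 (0.356, 0.285 to 0.442), Acod1 (0.410, 0.326 to 0.513), Olr1 (0.444, 0.378 to 0.520), Lonrf3 (0.479, 0.409 to 0.559) and Tnfaip2 (0.481, 0.416 to 0.554).

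**Figure D3:**
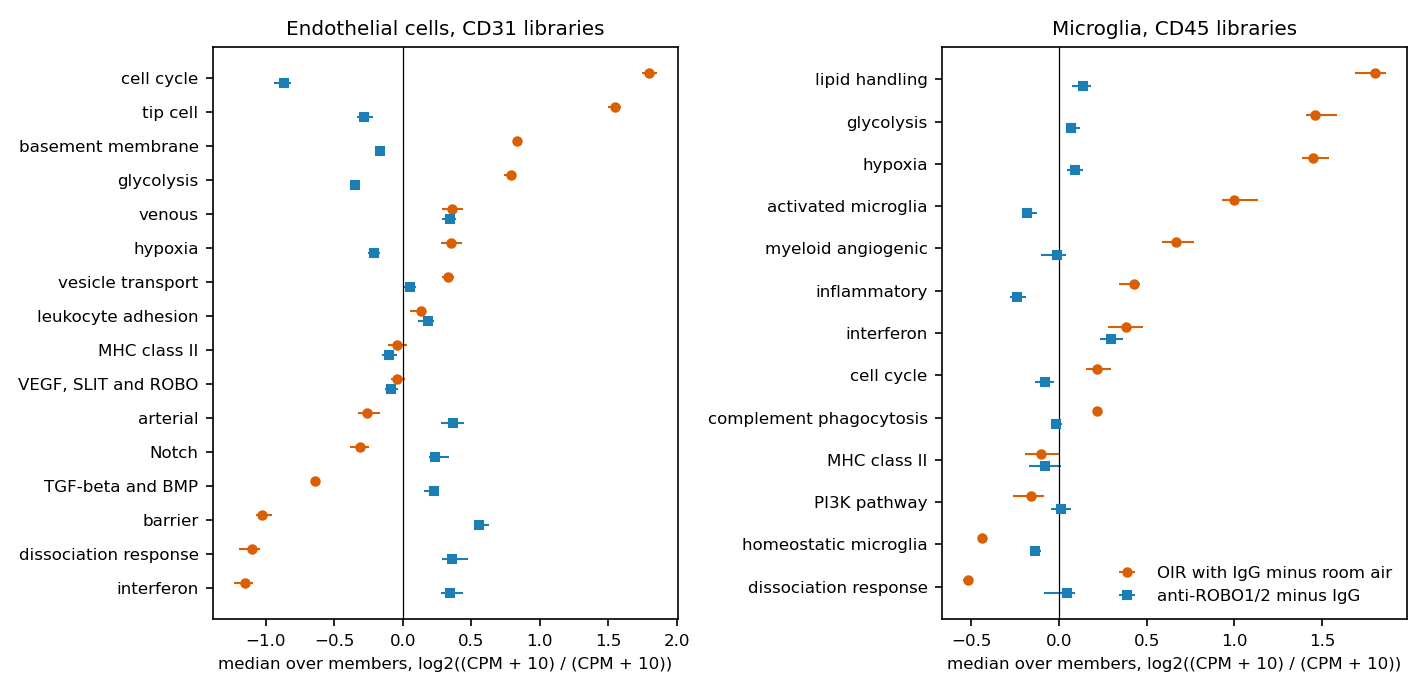
Median log2 ratio of each gene list in endothelial cells (CD31 libraries) and microglia (CD45 libraries), for IgG against room air (circles) and anti-ROBO against IgG (squares), with 95% counting intervals as lines. The cell-cycle list in endothelial cells lies at 1.79 in the former and -0.87 in the latter comparison. Both comparisons use the same IgG library of each enrichment, so opposite signs can come from that library alone.

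Differences in the share of leukocytes other than microglia in the CD45 libraries depended on the minimum depth of a cell and on 1 unnamed cluster. At each library's own threshold the share was 24.6% in room air (110 of 447, 20.7 to 28.9%), 25.8% with IgG (142 of 550, 22.2 to 29.7%) and 24.0% with anti-ROBO (149 of 620, 20.7 to 27.6%). The differences were 1.21 points (-4.24 to 6.57) between IgG and room air and -1.79 points (-6.76 to 3.16) between anti-ROBO and IgG, neither detectable at this number of cells. With the same minimum of 1000 UMIs per cell in every library they were -1.004 and 4.99 points, and with one of 2000 UMIs 7.41 and 8.15 points, and of these 4 values only the first lay inside the intervals. Macrophages with Mrc1 and Lyve1 were the largest part, with 63, 92 and 113 cells. A further leukocyte cluster, led by Apoc2, Arg1 and MHC class II genes, was given no class because it scored highest for microglia while a macrophage marker, F13a1, was among its leading genes. With it counted as non-microglial, the share with anti-ROBO was 37.4% and the difference from IgG 9.07 points (3.95 to 14.1). Of its 132 anti-ROBO cells, 125 were classed as macrophages at the minimum of 1000 UMIs and 124 as T or NK cells at that of 2000; without the cluster's cells the differences were -1.605 and -1.508 points at the former and 6.69 and 1.511 points at the latter. With that cluster among the leukocytes, sub-clusters made without the listed genes gave a homeostatic group of 56.9% in room air, 30.6% with IgG and 30.3% with anti-ROBO. The group named activated held 0% in room air, which allows 0.659%, and 13.2% and 13.96% in the other libraries. Mmp12 led it, and of the activation list only Spp1 was among its 10 leading genes, beside Bnip3, Egln3, Pgk1 and Adm of the hypoxia list. The unnamed group led by Hmox1, given below, also scored highest for activation, but at 0.154, under the minimum of 1 for a name. Whether it held activated microglia was not tested. The 0% counts only the group named activated and may not cover all activated microglia. Other sub-clusters differed between IgG and anti-ROBO: one led by Arg1 and Apoc2 held 2.11 and 13.7%, one of MHC class II genes 0.351 and 2.66%, one led by Hmox1 7.38 and 2.53%, and one led by haemoglobin genes 16.7 and 9.04%. In room air these held 1.099%, 0 (which allows 0.659%), 10.1% and 1.98%. The Hmox1 group had a median of 5469 UMIs. That is near the lowest UMI total called a cell, 4063 with IgG, 2626 in room air and 4364 with anti-ROBO, which bears on its shares.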

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

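All tests in this part were chosen after the result was seen, as was the limit of 5% of a library's cells that picked the clusters given here.

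A cluster led by Apoc2, Arg1, H2-Aa and other MHC class II genes made up 6.41% of the anti-ROBO CD45 library (132 of 2058 cells), against 0.446% of the room-air CD45 library (8 of 1793). With IgG it held 19 of 1660 cells, 1.14%, and of all leukocytes its share was 3.34% with IgG and 17.6% (14.9 to 20.5%) with anti-ROBO. In the anti-ROBO library its cells carried Arg1, an arginine-degrading enzyme of macrophages (chromosome 10, 24915221 to 24927484), at 438 CPM, against 20.05 in microglia and 78.7 in macrophages. The MHC class II gene H2-Aa stood at 1337 CPM against 1.07 and 7.83, and Ccr2, a receptor of blood monocytes, at 166 CPM against 1.36 and 0.921. P2ry12, a microglial gene (chromosome 3, 59216272 to 59262871), stood at 151 CPM against 765 in microglia, and Mrc1 at 60.4 CPM against 2343 in macrophages. Among leukocyte sub-clusters made without the listed genes, Arg1 and MHC class II genes led separate groups, of 103 and 20 anti-ROBO cells, so the cluster may not be a single kind of cell.

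Doublets of microglia and macrophages would hold more UMIs than either, but the cluster's median was 0.917 times (0.857 to 0.996) the larger median of both classes, and a mixture of both could not reach its levels of H2-Aa and Ccr2. Barcodes swapped from another library would hold more UMIs there, and 0 of its 132 barcodes did, which allows 2.27%. A larger share of blood would bring more monocytes, neutrophils and lymphocytes, but among leukocytes outside the cluster these were 5.81% with anti-ROBO (36 of 620) and 9.09% with IgG (50 of 550), a difference of -3.28 points (-6.41 to -0.276). With the same minimum in every library it was -1.67 points (-3.57 to 0.104) at 1000 UMIs, -3.05 (-5.78 to -0.481) at 2000 and -3.83 (-6.62 to -1.29) at the largest threshold. No value lay above 0, but 1 interval reached it, so a larger share of blood stays open. An effect of the antibodies on monocyte-derived or antigen-presenting cells stays open as a hypothesis, as does a difference between the pools of retinas, which 1 library per group does not separate from treatment and which was not tested.

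A cluster led by Dct, Ptgds, Cox8b, Oca2 and Pmel made up 10.5% of the anti-ROBO CD31 library (152 of 1448 cells) and 0 of the 1838 cells of the room-air CD31 library, which allows 0.163%. It scored highest for endothelial cells but was given no class, since pigment-cell markers led it, and Il1r1 and Pmel were also among the leading genes of the clusters taken mostly from that library's endothelial cells. Counted as endothelial, it gave medians between anti-ROBO and IgG of -0.94 for the cell cycle and -0.33 for tip cells. Whether its cells, or those of both named clusters, were doublets or came from outside the retina was not tested, and this bears on every endothelial value of that library.

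Cell-cycle genes and 5 of 20 tip-cell genes were lower in anti-ROBO than in IgG endothelial cells, with medians of -0.87 (-1.30 to -0.50) and -0.28 (-0.49 to -0.07); the intervals of these and the next medians are over redrawn cells. A difference in depth could have given this. With the largest library's UMI threshold applied to every library the cell-cycle median was -0.90 (-1.33 to -0.49), from 262 anti-ROBO and 434 IgG cells. That equalised the lowest UMI total but not the depth above it, so this test could not settle depth. Without both clusters taken mostly from the anti-ROBO CD31 library the cell-cycle median was -0.81 (-1.23 to -0.40), so those clusters were not its whole cause. These changes were not made together. In these settings the tip-cell medians were -0.21 (-0.45 to 0.013) and -0.18 (-0.37 to 0.041). Since both intervals reached 0, both explanations stay open for that list. In the CD45 libraries, with 81 and 58 endothelial cells, the medians were -0.29 (-1.35 to 0.81) for the cell cycle and -0.29 (-0.83 to 0.24) for tip cells. There 30 of the 81 anti-ROBO cells lay in a sub-cluster, led by Rgs5 and Serpine2, with 0 cells in the other 5 libraries, and without it the medians were -0.23 (-1.35 to 0.94) and -0.29 (-0.83 to 0.27). Dividing cells, 1 of 81 and 4 of 58, differed by -5.66 points (-15.3 to 1.19). The cells are too few to show whether the direction is that of the CD31 library alone, which stays open. Less vessel growth with the antibodies stays a hypothesis, and a difference between pools of retinas, which the CD31 and CD45 libraries may share, was not tested. Neither was a peculiarity of the IgG CD31 library, which both comparisons of endothelial cells use.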

How the results depend on the processing

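The CD45 libraries with at least 50 cells, with or without a sub-cluster found only in that of anti-ROBO, all changes of clusters, the minimum of 2000 UMIs, the largest library's threshold, all depth minimums without the Arg1 cluster's cells, the removal of the highest 5% of doublet scores and the free-RNA profile of 100 to 300 UMIs were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers and the values come from no test; the CD31 and CD45 libraries of a condition may come from the same retinas. The planned use of the other enrichment with at least 100 cells gave no value, since it held 57 to 81 endothelial cells and 4 to 10 microglia. Of 80 alternatives for the main list medians and shares between IgG and room air, 60 stayed within counting error, 18 moved beyond it and 2 turned sign; between anti-ROBO and IgG 59, 19 and 5 of 83 did. For named genes in endothelial cells 0 of 780 and 0 of 528 alternatives turned sign, and in microglia 3 of 528 and 0 of 264. These counts leave out ROBO and SLIT genes at their free-RNA level, kept apart after they had turned: 2 of 24 and 6 of 24 alternatives in endothelial cells and 4 of 33 and 9 of 33 in microglia. Slit2 in endothelial cells, given no direction, had log2 values of 0.06 between IgG and room air and 0.09 between anti-ROBO and IgG, which became 0.64 and -0.64 with the planned free RNA subtracted, and 0.28 and -0.28 with that of 100 to 300 UMIs. Where a value moved or turned, the cause was not tested except for leukocytes.

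For endothelial cells between IgG and room air, the tip-cell median (1.55) was 1.62 with median-of-ratios scaling, 1.62 with equal weight of cells, 1.62 with CPM + 1 and 1.40 in the CD45 libraries. The cell-cycle median (1.79) was 1.53 with equal weight, 4.16 with CPM + 1 and 0.70 in the CD45 libraries. Between anti-ROBO and IgG, the tip-cell median (-0.28) was -0.60 with equal weight, -0.18 without the clusters mostly of the anti-ROBO CD31 library and -0.21 with the largest threshold. The cell-cycle median (-0.87) was -0.81 with equal weight, -1.27 with CPM + 1, -0.81 without those clusters, -0.94 with the unnamed Dct cluster, -0.29 in the CD45 libraries, -0.23 there without that sub-cluster and -0.79 with at least 1000 UMIs.

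For microglia between IgG and room air, the homeostatic median (-0.44) was -0.46 with free RNA subtracted, -0.35 with median-of-ratios scaling and -0.38 with equal weight. The activation median (1.00) was 1.22 with CPM + 1, 1.15 with at most 10% mitochondrial UMIs, 1.14 with doublets kept and 1.21 without the highest 5% of doublet scores. Cd74 (1.37) turned to -0.053 with at most 10% mitochondrial UMIs and -0.062 with doublets kept, and Cartpt (2.60) to -0.10 without the highest 5% of doublet scores. Between anti-ROBO and IgG, the homeostatic median (-0.14) was -0.18 with median-of-ratios scaling, -0.19 with at least 1000 UMIs, -0.33 with at most 10% mitochondrial UMIs, -0.34 with doublets kept and -0.18 with at least 2000 UMIs. In the mitochondrial and doublet settings 600 and 607 anti-ROBO cells were classed as microglia, in place of 471. The activation median (-0.18) was -0.22 with median-of-ratios scaling, -0.25 with equal weight and -0.12 with at least 2000 UMIs.

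The difference in dividing endothelial cells between IgG and room air (10.3 points) was 15.2 at 2000 UMIs per cell and 5.14 in the CD45 libraries. That between anti-ROBO and IgG (-7.47) was -3.75 with at least 1000 UMIs, from 2549 and 708 cells. The leukocyte difference between IgG and room air (1.21) turned to -1.004 with at least 1000 UMIs and was 7.41 with at least 2000; without the Arg1 cluster's cells these were -1.605 and 6.69. Between anti-ROBO and IgG (-1.79) it turned to 9.07 with the Arg1 cluster counted, 4.99 with at least 1000 UMIs, 8.15 with at least 2000 and 1.33 with the largest threshold and was lowest, at -5.31, with at most 10% mitochondrial UMIs. Without the Arg1 cluster's cells it was -1.508 with at least 1000 UMIs, 1.511 with at least 2000 and -1.14 with the largest threshold. With at most 10% mitochondrial UMIs, 745 anti-ROBO and 553 IgG cells were classed as leukocytes, in place of 620 and 550. At a sub-cluster resolution of 0.8, the tip-cell group held 31.8, 1.32 and 10.6% (IgG, room air, anti-ROBO) and the cell-cycle group 18.9, 0 and 4.82%. The arterial group, 8.64, 3.20 and 11.6% at 0.4, held 8.64, 4.33 and 7.83% with a separate group of 3.82% from anti-ROBO. The homeostatic group split into groups of 22.3, 25.5 and 24.9% and of 7.03, 30.8 and 4.12%.

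Between anti-ROBO and IgG, other endothelial lists without the clusters mostly of the anti-ROBO CD31 library kept their sign except leukocyte adhesion (0.18), at -0.0057. In Müller glia of the CD31 libraries without the Optc cluster, and without the Optc and Crym clusters, the cell-cycle median (0.25) turned to -0.0499 and -0.0677, glycolysis (-0.08) to 0.0194 and 0.0461 and Lcn2 (1.28) to -0.37 and -0.48. The inflammatory median (-0.05) turned to 0.0282 without the Optc cluster and hypoxia (-0.10) to 0.0283 without both. In the CD45 libraries the cell-cycle median (0.022) turned to -0.11 and -0.14, and without both clusters hypoxia (0.042) to -0.0746 and glycolysis (0.016) to -0.0382.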

Other observations

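The test of free RNA and that of a held-out gene list in this part were written before their results were seen, and the gene groups below were chosen after their values were seen.

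Müller glia, the radial glia of the retina, carried more hypoxia and glycolysis transcripts in the IgG than in the room-air libraries, in both enrichments. These lists share members. The hypoxia median was 0.66 (0.61 to 0.72) in the CD31 and 0.56 (0.51 to 0.71) in the CD45 libraries, and the glycolysis median 0.64 (0.59 to 0.70) and 0.51 (0.46 to 0.58). Adm, a vasodilator peptide induced by hypoxia, had ratios of 434 (148 to 2106) and 51.9 (29.5 to 101), with 3 UMIs in the room-air CD31 library, and Ndufa4l2, a mitochondrial protein, 17.3 (15.4 to 19.6) and 10.5 (9.33 to 11.9). For genes named by the fixed rule in Müller glia, the same direction in both enrichments was a condition, so such agreement is no separate support. A Müller cluster led by Crym, Ndufa4l2 and A2m held 45 and 15 cells with IgG, 8 and 54 with anti-ROBO and 0 in both room-air libraries. Bipolar cells had hypoxia medians of 0.54 (0.44 to 0.63) and 0.32 (0.24 to 0.45) between IgG and room air, while rods had -0.02 (-0.12 to 0.09) and cones 0.17 (-0.04 to 0.26) in the CD45 libraries. Cones of the CD31 libraries had 0.14 (0.03 to 0.22).

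Between anti-ROBO and IgG, the interferon median in Müller glia was 0.40 (0.20 to 0.50) in the CD31 and 0.64 (0.44 to 0.77) in the CD45 libraries. Lcn2, an iron-binding protein of reactive glia, had a ratio of 2.89 (2.46 to 3.399) in the CD31 and 21.3 (15.7 to 29.9) in the CD45 libraries. The rule for named genes required this shared direction. A cluster led by Optc and Crhbp was named Müller glia by a score of 1.013 against a minimum of 1, with 0 Müller markers among its 10 leading genes, so its class is uncertain. It held 40 of the 150 anti-ROBO and 11 of the 367 IgG cells of the CD31 libraries, against 31 of 322 and 12 of 196 in the CD45 libraries. Without it the interferon median was 0.075 in the CD31 and 0.74 in the CD45 libraries, and the log2 value of Lcn2 was -0.37 in place of 1.28 and 3.57 in place of 3.42, so in the remaining Müller glia of the CD31 libraries Lcn2 was not higher with anti-ROBO and the interferon median lay near 0. Selenbp1 had ratios of 4.11 (3.22 to 5.29) in rods and 4.73 (3.60 to 6.30) in cones. The dissociation list had medians of -0.86 (-1.16 to -0.69) in cones of the CD45 libraries and of -0.58 (-0.82 to -0.47) and -0.49 (-0.73 to -0.23) in bipolar cells of the CD31 and CD45 libraries. Of the cones compared, 3 of 118 IgG and 0 of 135 anti-ROBO cells lay in a cluster led by Prss56, which also led a Müller cluster. Its median was 37964.5 UMIs, and its part in the cone values was not tested. In macrophages Slit1 stood at 12.9, 9.13 and 5.06 CPM with IgG, in room air and with anti-ROBO, from 30, 10 and 11 UMIs, against free-RNA levels of 0.462, 0.240 and 0.173 CPM.

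Several genes named between anti-ROBO and IgG, Tsc22d3, Zbtb16, Sult1a1, Pik3ip1, Fkbp5 and Lcn2, are known from responses to glucocorticoids, and a candidate explanation was such a response across cell classes. A list of 12 other glucocorticoid genes, of which 7 to 12 were measured in each of 8 pairs of class and enrichment, had a median of 0.021 over the pairs, below the 0.1 set beforehand as the bound against it, so the test of a response across classes came out negative. Values for single pairs, seen afterwards, ranged from -0.17 (-0.46 to -0.0003) in cones to 0.49 (0.44 to 0.56) in endothelial cells, and 5 of the 8 lay above 0. In endothelial cells 11 of 12 and in microglia 10 of 11 measured genes lay above 0, the latter with a median of 0.25 (0.15 to 0.32), and both medians lay above those of all 10000 random gene lists of the same size and mean level. In Müller glia the median was 0.15 (0.07 to 0.23) in the CD31 libraries, above 99.3% of random lists, and 0.04 (-0.03 to 0.15) in the CD45 libraries, with the Optc cluster included. A response in some classes only was not what the test addressed and stays open. In endothelial cells the first genes had a median of 1.299 before and 1.31 after subtraction of free RNA. Genes named in that class had already been required to reach at least 2 times a free-RNA profile. The share subtracted was 1.003% with IgG and 2.08% with anti-ROBO. Little change was therefore possible, and this test could not decide whether free RNA played a part.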
